A study of Homo sapiens with 6 samples.

How the data were processed

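Poly(A) RNA of 6 HUVEC samples was measured by RNA sequencing, 3 transfected with scrambled siRNA (siControl) and 3 with SOX4 siRNA (siSOX4). Per the labels' protocols, cells grew in 100 mm dishes, RNA was taken 48 hours after transfection, and 50-base paired-end reads were made. Groups and replicate numbers were taken from the sample titles.

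The authors deposited one table of whole-number read counts per gene for the 6 libraries, with gene symbols as names and no normalization. The submitters' processing notes name FastQC, MultiQC, STAR, DESeq2 and DESeq, and the genome build mm10, a mouse build. The table holds human gene symbols (3 of 56609 are written as mouse symbols are), so that build does not match the symbols, and no coordinates were used. The counting tool, the versions, the annotation and whether counting used strand are not given in the sources used here. Genes that overlap another gene or share sequence with a close copy are therefore uncertain.

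The table had 56609 genes, of which 34193 had a count in at least 1 library. Of the symbols, 35017 matched a current RefSeq symbol and 1455 a synonym, 64.4% in all, and the match was used for gene types, older names and overlapping genes. Library totals ran from 40124105 to 55953989 counts, which puts the limit that a count of 0 allows (3 counts) at 0.0536 to 0.0748 CPM. Intervals on counts are exact at 95% and cover counting error only. Replicate pairs within a group differed by more than sampling noise, with chi-square per degree of freedom from 7.73 to 49.7, so each library counted as 1 replicate. Log2 CPM of replicate pairs correlated across genes at 0.989 to 0.995.

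Tests used edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr on group (minimum count of 10, minimum total of 15), libraries were scaled by TMM with factors of 0.974 to 1.02, and dispersions were estimated with robust settings (biological coefficient of variation 0.122). Robust quasi-likelihood fits without covariates were tested by the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over 16626 genes and a threshold of 0.05. CPM are TMM-scaled. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The 95% interval of SOX4 rests on it and on normal quantiles, which makes it narrower than the F test would allow with so few libraries. Group membership of the 6 libraries was the only term, since nothing says that equal replicate numbers mark a shared culture or day.

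Before the data were examined, 28 gene lists were fixed from general knowledge: SOX family, SOX4 literature targets, endothelial identity, arterial and Notch, venous and lymphatic, tip cell and angiogenic, mesenchymal transition, TGF-beta and BMP targets, interferon response, NF-kB inflammation, mitosis, DNA replication, p53 targets, Wnt targets, YAP and TEAD targets, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and integrated stress, extracellular matrix, cell junctions, vasoactive and haemostasis, cilium and microtubule, smooth muscle and pericyte, fibroblast, blood cell, epithelial cell, mitochondrially encoded transcripts and histones. The 27 lists with at least 5 measured members were tested by camera in limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the lists, the SOX family without SOX4. Of all list members, 3 histone genes had no unambiguous row. Camera compares a list with the other genes, while fry tests whether its members move on balance one way and compares them with no other genes.

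Genes to name were also chosen by a rule fixed beforehand. It took SOX4, then the 10 largest increases and 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM and non-overlapping groups, then up to 4 members of each list with the smallest p, and every measured SOX family member. Outside that rule, DLL4 and CXCR4 were named after their values were seen, as were the members of symbol families in the closing section. Sex-linked marker genes were left out of all named results, and some genes that the rule takes are not reported here.

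The procedure was tested on simulated counts for siSOX4 against siControl over 16626 genes, in 3 runs with 200 changed genes each. The edgeR test recovered 47.3% of genes changed 1.5-fold, 70.6% of those changed 2-fold and 92.9% of those changed 4-fold, and 9.27% of its calls were false, above the nominal 5%. DESeq2 recovered 54.7%, 74.6% and 90.9% with 19.1% false calls, and limma-voom 41.8%, 70.6% and 92.9% with 9.49%. The simulation drew genes independently and changed far fewer of them than were called in the data, so these rates do not carry over to those calls. Camera was run on simulated lists only with the preset correlation.

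Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other scalings (RLE factors, upper-quartile factors, library totals), no filter or a mean count of at least 50, tests against a fold of 1.2 or 1.5, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. An alternative without siControl 3 and siSOX4 2 together, and one with the mean of the mitosis list as a covariate, were added after the data were seen, as was an estimated correlation in each fit with libraries left out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.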

Results

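Poly(A) RNA was sequenced from HUVEC, primary endothelial cells of the human umbilical vein that the labels describe as pooled. Cells received either a scrambled siRNA (siControl, 3 libraries) or an siRNA against SOX4 (siSOX4, 3 libraries) and were harvested 48 hours later. SOX4 is a transcription factor of the SRY-box (SOX) family, and the comparison asked which transcripts differ once it is depleted. The siControl libraries held 55953989, 42096685 and 45093052 counts and the siSOX4 libraries 40662206, 40124105 and 48852789 counts, and 16626 genes had enough counts to be tested. Levels are given as counts-per-million (CPM), mean ± SD with n = 3 per group, and log2 fold changes as siSOX4 against siControl ± SE. Nothing in the labels says that the replicates came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. The library numbers run from 1 to 3 in siControl and from 7 to 9 in siSOX4, so an effect that follows library order cannot be told apart from the siRNA.

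The targeted transcript was lower in every siSOX4 library. SOX4 had 11160, 9372 and 11374 counts in the siControl libraries and 1794, 2070 and 1826 in the siSOX4 libraries. Its level fell from 225 ± 28.2 to 44.5 ± 8.04 CPM (SD, n = 3 each), which left 19.7% of the control level (95% interval from normal quantiles 16.2% to 24.0%). The log2 fold change was -2.34 ± 0.15, with an adjusted p of 0.00011 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

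Other members of the SOX family moved apart. SOX5, a family member without a transactivation domain of its own, fell at a low level, from 178 counts over the siControl libraries to 24 over the siSOX4 libraries, a depth-scaled ratio of 6.72 (exact 95% interval 4.37 to 10.8, counting error only). SOX12, which belongs to the same SoxC subgroup as SOX4, rose from 43.4 ± 2.10 to 60.3 ± 4.74 CPM (SD, n = 3), and SOX8 rose by 0.94 ± 0.24 on the log2 scale. The endothelial members did not pass the test: SOX18 had a log2 fold change of -0.64 ± 0.20 (edgeR adjusted p = 0.060), SOX17 of -0.23 ± 0.12, and SOX7 of -0.08 ± 0.086. SOX6, SOX13 and SOX15 did not pass either, with log2 fold changes of -0.51 ± 0.28, -0.07 ± 0.086 and -0.60 ± 0.34. Of the 9 members measured besides SOX4, 2 rose and 1 fell, and 2 rose and 2 fell adjusted over the list alone, the second being SOX18. DESeq2, limma-voom, library totals, no filter and the replicate block each had 2 members lower, with 2 higher, or 1 with the block. RLE and upper-quartile factors kept 1 lower, and a mean count of at least 50 had 0 of 6 measured. SOX8 was the less stable call: 1 member rose without siControl 1, siControl 2, siSOX4 1 or siSOX4 3, and 3 members fell without siSOX4 2. As a set the family was not past the threshold in limma's camera test (adjusted p = 0.38).

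Among 9 measured genes described in the general literature as targets of SOX4, 3 fell and none rose by edgeR's adjusted p, and 4 fell adjusted over the list alone. MEX3A, an RNA-binding protein, fell 2.97-fold, from 42.6 ± 1.04 to 14.3 ± 0.834 CPM (SD, n = 3). TEAD2, a DNA-binding partner of YAP, fell 1.92-fold, from 66.1 ± 4.46 to 34.4 ± 3.27 CPM. EZH2, the methyltransferase of the Polycomb complex, had a log2 fold change of -0.55 ± 0.15 and lost its call without siControl 1, siControl 2, siSOX4 2 or siSOX4 3 (edgeR adjusted p = 0.11, 0.12, 0.062 and 0.11). DICER1, the endonuclease of microRNA maturation, had -0.35 ± 0.11 (edgeR adjusted p = 0.065). At an unadjusted p 1 member was higher, and DESeq2 called 2 higher; without siControl 3 or siSOX4 2, edgeR called 1 higher. The camera test of the list gave an adjusted p of 0.082, and 0.049 with the replicate block. Without the block it gave 0.817 with an estimated correlation. The fry test, which asks whether the members move on balance one way without comparing them with other genes, gave an adjusted p of 0.029.

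Across the transcriptome, 3119 of 16626 genes (18.8%) changed at an edgeR adjusted p under 0.05, 1623 of them higher and 1496 lower in siSOX4. The balance of directions depended on the processing: upper-quartile factors gave 1429 higher and 1649 lower, and a mean count of at least 50 gave 1415 and 1436. Most changes were modest: 616 genes were at least 1.5-fold higher and 701 at least 1.5-fold lower, and 220 and 324 at least 2-fold. In 6230 tested genes (37.5%) all libraries of one group lay on the same side of all libraries of the other, where chance gives 10%. The count depended on single libraries. It was 1784 without siControl 1, 1430 without siControl 2, 1635 without siSOX4 1 and 1633 without siSOX4 3, with 749 to 903 genes higher and 681 to 881 lower in these 4 fits. Without siControl 3 it was 2989 and without siSOX4 2 it was 3321.

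**Figure D1:**
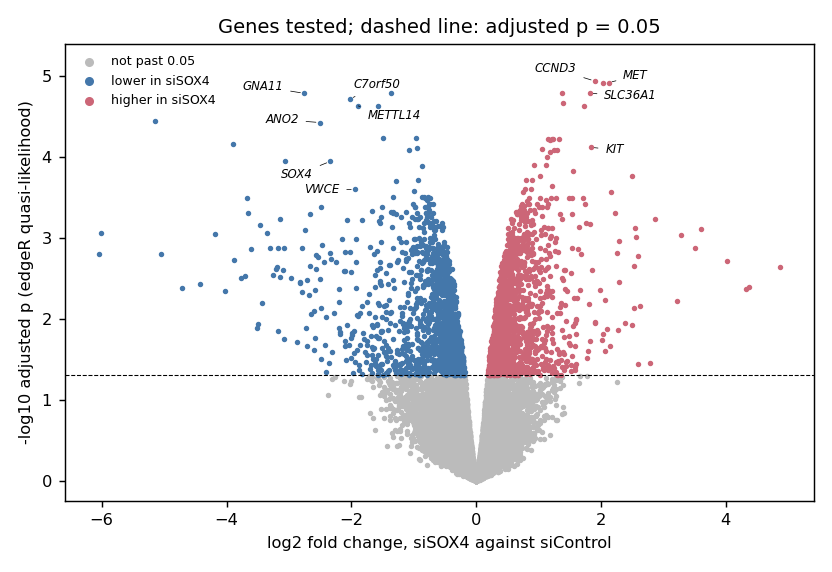
Log2 fold change in siSOX4 against siControl (horizontal axis) and -log10 of the edgeR adjusted p (vertical axis) of the genes tested, blue where lower and red where higher at an adjusted p under 0.05. GNA11, ANO2 and SOX4 lie at the upper left at -2.76, -2.51 and -2.34, and MET and CCND3 at the upper right at 2.12 and 1.90.

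Among the genes with the largest increases were those of receptors, a protease and a cell cycle regulator. MET, the receptor of hepatocyte growth factor, rose 4.35-fold, from 61.5 ± 4.62 to 268 ± 20.8 CPM (SD, n = 3). PLAT, tissue plasminogen activator, rose 4.08-fold, from 34.0 ± 2.96 to 139 ± 5.06 CPM. CCND3, cyclin D3, rose 3.72-fold, from 28.4 ± 0.707 to 106 ± 4.86 CPM. KIT, the receptor of stem cell factor, rose 3.57-fold, and SLC36A1, a lysosomal amino acid transporter, 3.53-fold. ADTRP, a regulator of tissue factor pathway inhibitor, the dynein chain gene DYNC1I1, the keratin gene KRT15 and PLEK2, a pleckstrin, rose 3.12-fold to 3.40-fold. The edgeR adjusted p of these genes ran from 1.1e-05 (CCND3) to 0.00072 (PLEK2).

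Among the largest decreases were genes of signalling, ion transport, adhesion and RNA modification, which were not tested as classes. GNA11, the G protein subunit alpha 11, fell 6.77-fold, from 76.7 ± 4.71 to 11.3 ± 1.93 CPM (SD, n = 3). ANO2, a calcium-activated chloride channel, fell 5.70-fold, from 59.7 ± 5.26 to 10.5 ± 1.96 CPM. METTL14, a subunit of the methyltransferase that makes N6-methyladenosine in mRNA, fell 3.71-fold, from 28.3 ± 0.116 to 7.64 ± 0.723 CPM. DSP, the desmosomal protein desmoplakin, fell 4.36-fold and C7orf50 4.06-fold. GCNA, VWCE and KIAA1211, an actin regulator now named CRACD, had log2 fold changes of -2.25 ± 0.29, -1.94 ± 0.15 and -1.66 ± 0.15. The edgeR adjusted p of these genes ran from 1.6e-05 (GNA11) to 0.0026 (DSP). IFI44L, an interferon-stimulated gene, fell 3.14-fold (edgeR adjusted p = 0.031) from a control level of 186 ± 107 CPM, and its adjusted p was 0.055 without siControl 1, 0.072 without siSOX4 1, 0.12 without siSOX4 2 and 0.11 without siSOX4 3. Other annotated genes overlap C7orf50 (among them GPER1 and GPR146), MET, CCND3, SLC36A1, ADTRP, DYNC1I1, KRT15, PLEK2, DSP, ANO2 and KIAA1211, and whether counting used strand is not given in the sources used here, so shared reads cannot be separated. The siRNA sequences are not given in the sources used here, and matches of the siRNA to transcripts other than SOX4 were not analysed.

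**Figure D2:**
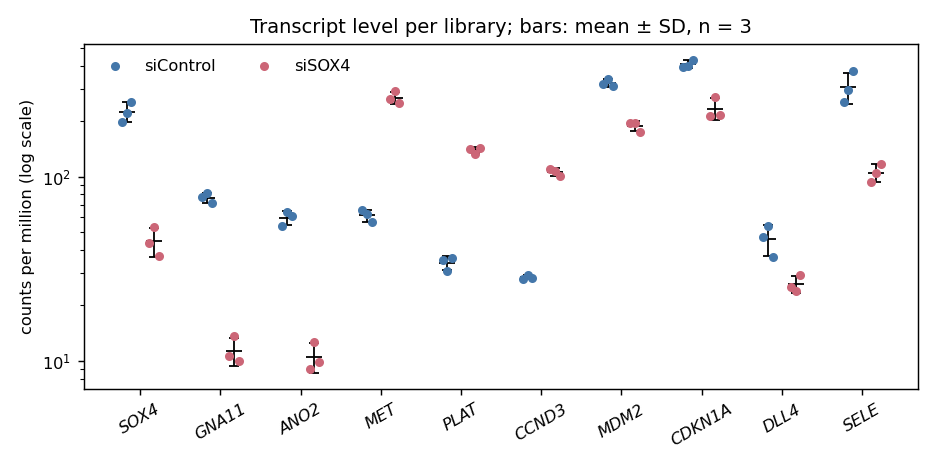
Transcript level in CPM (vertical axis, log scale) of 10 genes in each of the 3 siControl (blue) and 3 siSOX4 (red) libraries, with bars for the mean ± SD. In each gene shown the libraries of one group lie on one side of those of the other: SOX4, GNA11, ANO2, MDM2, CDKN1A, DLL4 and SELE lower, and MET, PLAT and CCND3 higher in siSOX4.

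Transcripts of the p53 target list were lower as a group in siSOX4. Of 24 measured members 15 fell by edgeR's adjusted p, and 18 adjusted over the list alone; none rose by edgeR or DESeq2, and none was higher at an unadjusted p under 0.05. MDM2, a ubiquitin ligase, fell from 322 ± 15.1 to 188 ± 11.4 CPM (SD, n = 3), and CDKN1A, the cell cycle inhibitor p21, from 409 ± 19.6 to 234 ± 31.9 CPM. BTG2, an antiproliferative gene, and CCNG1, cyclin G1, fell 1.75-fold and 1.41-fold. The median log2 fold change of the list was -0.44, and the mean of its members was 6.01, 6.07 and 6.03 log2 CPM in the siControl libraries and 5.57, 5.69 and 5.54 in the siSOX4 libraries. In camera with its preset correlation the list had an adjusted p of 6.4e-09 over 27 lists. With an estimated correlation the list was not past the threshold (camera adjusted p = 0.795), while fry gave an adjusted p of 0.016. None of the 5 lists past the threshold with the preset correlation, all of them lower, was past it with an estimated one. With an estimated correlation 0 lists were past it in any fit with 1 library left out, so the list calls gained in those fits were lost with it too. That setting also passed 0 lists in all 6 libraries, and it was not tried on simulated lists. Its losses therefore cannot decide whether a list call holds. The estimated correlations were 0.152 for p53 targets, 0.765 for interferon, 0.628 for NF-kB, 0.0655 for Notch and 0.0933 for YAP and TEAD. All lie above the preset 0.01, so the camera p-values with the preset correlation may be too small. With that preset value, a split of the libraries that mixes the 2 groups passed as many as 16 lists.

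**Figure D3:**
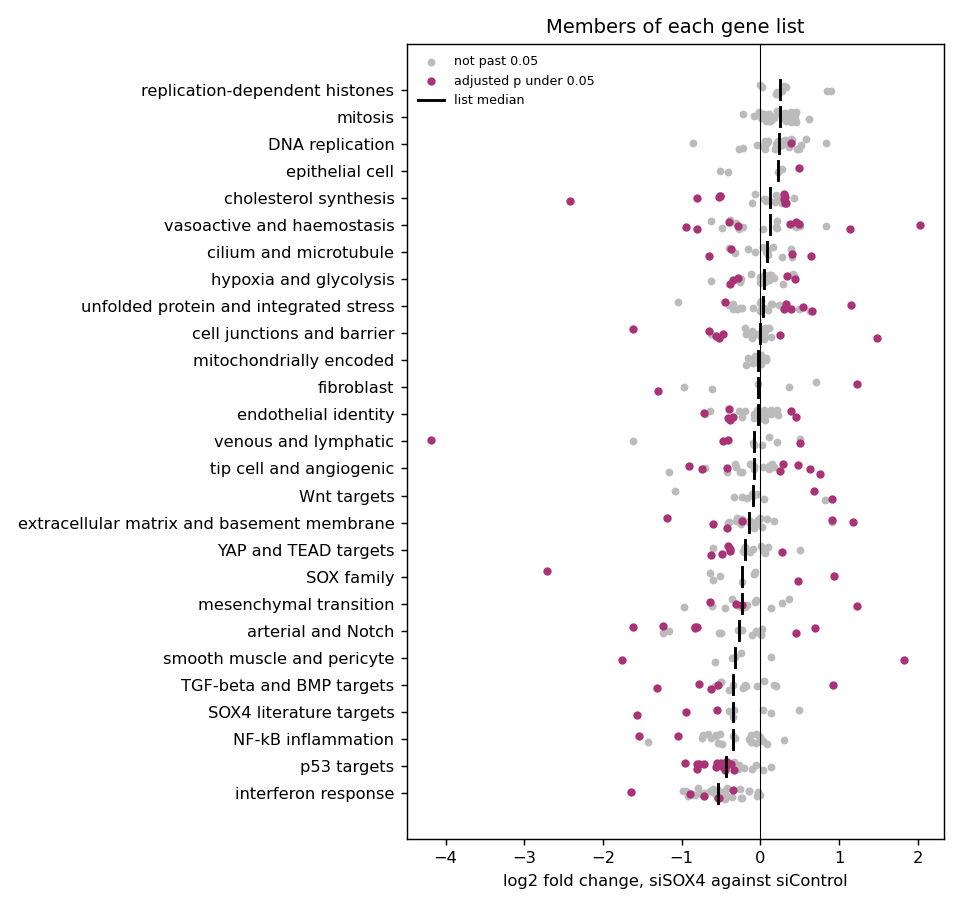
Log2 fold change in siSOX4 against siControl (horizontal axis) of every measured member of the 27 gene lists tested, purple where the edgeR adjusted p is under 0.05, with a black bar at the list median. The interferon and p53 lists have the lowest medians, at -0.53 and -0.44, with 6 of 37 and 15 of 24 members past the threshold.

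Notch pathway and arterial genes were also lower as a list. LFNG, a glycosyltransferase that modifies Notch receptors, fell from 21.3 ± 0.679 to 11.9 ± 0.676 CPM (SD, n = 3). The Notch targets HES4 and NRARP fell 2.35-fold and 1.78-fold, the ligand gene DLL4 1.75-fold, and GJA4, which encodes the arterial gap junction protein connexin 37, 3.06-fold. The ligand gene JAG1 went the other way and rose 1.62-fold, from 81.4 ± 11.9 to 132 ± 8.92 CPM, and CXCR4, a chemokine receptor, rose 1.36-fold. Of 20 measured members 2 rose and 5 fell by edgeR's adjusted p, and 2 rose and 7 fell adjusted over the list alone. Without siControl 3, 8 fell, and without siControl 1, siControl 2, siSOX4 1 or siSOX4 3 only 1 rose. The camera test gave an adjusted p of 0.010 with a median log2 fold change of -0.27. It was lost with an adjusted p = 0.817 with an estimated correlation, and fry gave 0.029.

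Markers of endothelial cells did not shift as a list. Of 26 endothelial identity genes 2 rose and 5 fell, and 2 rose and 7 fell adjusted over the list alone, with a median log2 fold change of -0.03 (camera adjusted p = 0.38). EGFL7, a secreted endothelial protein, and FLI1, an ETS transcription factor, fell 1.31-fold and 1.32-fold, and ICAM2, an adhesion molecule, rose 1.31-fold. Without siControl 2 the count of members that fell was 2, and without siSOX4 3 it was 3, and the list was past the threshold without siSOX4 2 (camera adjusted p = 0.026, median -0.08). Among 11 venous and lymphatic genes 1 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.55). APLNR, the apelin receptor, fell from 184 counts over the siControl libraries to 9 over the siSOX4 libraries, a depth-scaled ratio of 18.5 (exact 95% interval 9.54 to 41.1, counting error only). NR2F1, a nuclear receptor, rose 1.41-fold. The venous count of members that fell was 1 without siControl 2, siSOX4 1 or siSOX4 3, and 2 rose without siSOX4 1.

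Genes of sprouting tip cells went both ways. APLN, which encodes the ligand of the apelin receptor, fell from 393 ± 46.8 to 210 ± 5.33 CPM (SD, n = 3). ANGPT2, the TIE2 ligand angiopoietin 2, rose from 92.0 ± 7.82 to 155 ± 13.7 CPM, PGF, placental growth factor, 1.40-fold, and PLAUR, the urokinase receptor, 1.55-fold. Of 23 members 5 rose and 3 fell by edgeR's adjusted p, and 5 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.60). The number that rose was 3 without siControl 1, siControl 2, siSOX4 1 or siSOX4 3, and the number that fell was 5 without siControl 3 and 6 without siSOX4 2.

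Genes of vascular tone and clotting included some of the larger changes. Besides PLAT, KLF2, a transcription factor induced by flow, rose from 11.6 ± 0.158 to 25.6 ± 7.66 CPM (SD, n = 3), and PROCR, the protein C receptor, rose 1.30-fold. ACE, angiotensin-converting enzyme, fell from 72.0 ± 9.80 to 41.2 ± 7.18 CPM. Of 22 members 5 rose and 4 fell, and 7 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.60). In single-library omissions 1 fell without siControl 1, siControl 2 or siSOX4 3, and 7 fell without siSOX4 2. Of 23 junction and barrier genes 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.28). PTPRB, the endothelial tyrosine phosphatase VE-PTP, fell 1.44-fold, JUP, plakoglobin, 1.57-fold, and F11R, junctional adhesion molecule A, 1.48-fold. The number of junction genes that rose was 1 without siControl 1 or siControl 3, and 0 in edgeR without siControl 2, siSOX4 1 or siSOX4 3.

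Interferon-stimulated transcripts had a median log2 fold change of -0.53, but few passed the test one by one. Of 37 members 6 fell and none rose by edgeR's adjusted p, with the same counts adjusted over the list alone; at an unadjusted p under 0.05, 18 were lower and 0 higher, and DESeq2 called 15 lower and 0 higher. The 6 included IFI27, at 454 ± 103 against 275 ± 25.0 CPM (SD, n = 3). IFI27 lost its call without siSOX4 2 (edgeR adjusted p = 0.064) or siSOX4 3 (0.068). The number that fell was 3 without siControl 1, 14 without siControl 2, 3 without siSOX4 1, 2 without siSOX4 2 and 1 without siSOX4 3. The list mean was 5.16, 4.83 and 5.76 log2 CPM in the siControl libraries and 4.91, 4.65 and 4.66 in the siSOX4 libraries, so siControl 2 lay below siSOX4 1. Camera gave an adjusted p of 7.4e-06. The call was lost with an adjusted p = 0.817 with an estimated correlation, fry gave 0.43, and the median was -0.26 without siControl 3 and -0.23 without siControl 3 and siSOX4 2 together.

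Inflammatory transcripts induced through NF-kB contained a pair of clear decreases. SELE, the leukocyte adhesion molecule E-selectin, fell 2.93-fold to 105 ± 11.8 CPM (SD, n = 3), and CXCL1, a neutrophil chemokine, from 427 ± 95.9 to 207 ± 7.21 CPM. IL6 and IL1A, which encode cytokines, had log2 fold changes of -0.32 ± 0.099 and -0.73 ± 0.23 and did not pass the test (edgeR adjusted p = 0.056 and 0.066). Of 25 members 2 fell and 0 rose by edgeR's adjusted p, also adjusted over the list alone; 8 were lower and 0 higher at an unadjusted p under 0.05, and DESeq2 called 6 lower and 0 higher. The list had a median of -0.35 and a camera adjusted p of 0.019. It was lost with an adjusted p = 0.817 with an estimated correlation, and in fry (0.55). Without siControl 3 the camera adjusted p was 0.48 with a median of -0.14, and without siSOX4 1 it was 0.10. Without siControl 3 and siSOX4 2 together the median was -0.08.

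Some targets of YAP and TEAD and of TGF-beta and BMP signalling fell. Of 19 YAP and TEAD targets 1 rose and 5 fell, also adjusted over the list alone, with a median log2 fold change of -0.20 and a camera adjusted p of 0.029. That call was lost with an adjusted p = 0.817 with an estimated correlation, in fry (0.092), without siControl 3 (0.077) and without siSOX4 3 (0.13). AMOTL2, an angiomotin that binds YAP, fell 1.31-fold. The number that fell was 2 without siControl 1 or siControl 2, 1 without siSOX4 1 or siSOX4 3 and 8 without siSOX4 2, and none rose by edgeR without siControl 1, siControl 2 or siSOX4 1. Of 17 TGF-beta and BMP targets 1 rose and 4 fell, also adjusted over the list alone (median log2 fold change -0.34, camera adjusted p = 0.082). TGFBI, a matrix protein, rose from 28.5 ± 2.52 to 54.0 ± 2.55 CPM (SD, n = 3), while the BMP-induced inhibitors of DNA binding ID1, ID2 and ID3 fell 1.72-fold, 2.48-fold and 1.45-fold. Without siSOX4 2, 8 of these targets fell, and the list was past the threshold with no filter on low counts (camera adjusted p = 0.011) or the replicate block (0.049), and without siControl 2 (0.024) or siSOX4 2 (0.0081). These calls used the preset correlation, and an estimated one in all 6 libraries gave the list a camera adjusted p of 0.817.

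Calls of the matrix and mesenchymal lists depended on the filter and on single libraries. LAMA3, a laminin chain, rose from 6.88 ± 1.48 to 15.5 ± 3.11 CPM (SD, n = 3), and POSTN, the matrix protein periostin, fell 2.28-fold from 34.2 ± 5.41 CPM. Of 29 matrix genes 2 rose and 4 fell, and 2 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.11). The number of matrix genes that fell was 2 without siControl 1 or siSOX4 3, 1 without siControl 2 or siSOX4 1 and 8 without siSOX4 2, and 1 rose without siControl 1, siControl 2, siSOX4 2 or siSOX4 3. The matrix list was past the threshold with no filter on low counts (camera adjusted p = 0.0095), without siControl 1 (0.032) or without siSOX4 2 (0.0026). Of 17 genes of mesenchymal transition 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.070). These mesenchymal calls moved with single libraries: 0 fell in edgeR without siControl 2 or siSOX4 1, 1 fell without siControl 1 or siSOX4 3, 0 rose without siControl 1, siControl 2, siSOX4 1 or siSOX4 2, and 2 rose without siControl 3. As a list they were past the threshold with no filter (camera adjusted p = 0.012), a mean count of at least 50 (0.018) or the replicate block (0.047), and without siSOX4 2 (0.0083). The matrix and mesenchymal calls used the preset correlation, and an estimated one in all 6 libraries gave each list a camera adjusted p of 0.817.

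Metabolic and stress genes moved in both directions. PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, rose from 264 ± 8.97 to 586 ± 35.4 CPM (SD, n = 3), and PHGDH, the first enzyme of serine synthesis, rose 1.58-fold. Of 26 unfolded protein and integrated stress genes 6 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.38). The number of stress genes that rose was 3 without siControl 1, siControl 2, siSOX4 1 or siSOX4 3, while 4 fell without siSOX4 2 and 0 in edgeR without siControl 2, siSOX4 1 or siSOX4 3. In sterol synthesis LSS, lanosterol synthase, fell from 151 ± 10.6 to 86.3 ± 5.70 CPM and SREBF2, the transcription factor of the pathway, from 321 ± 9.74 to 224 ± 14.4 CPM. Of 23 cholesterol genes 5 rose and 5 fell, and 7 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.41, median 0.12 and mean -0.06). The sterol calls that rose numbered 3 without siControl 1 or siControl 3 and 0 in edgeR without siControl 2 or siSOX4 1, and those that fell 3 without siControl 1 or siSOX4 1 and 2 without siSOX4 3. Of 23 hypoxia and glycolysis genes 2 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.60). HK1, a hexokinase, rose 1.27-fold and PGAM1, a phosphoglycerate mutase, fell 1.30-fold. In this list 1 rose without siControl 1, siControl 2 or siSOX4 1, and 1 fell without siControl 1, siControl 2 or siSOX4 3.

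The Wnt and cilium lists were not past the threshold. Of 11 Wnt targets 2 rose and 0 fell by edgeR, by DESeq2, at an unadjusted p under 0.05 and adjusted over the list alone (camera adjusted p = 0.99, direction up, with a median of -0.09 and a mean of 0.04). The 2 were TCF7, a transcription factor of the pathway, and TNFRSF19, a receptor, and neither call was stable: 0 rose without siControl 1 or siControl 2, 1 rose without siControl 3, siSOX4 1 or siSOX4 3, and 2 and 1 fell without siControl 3 and siSOX4 2. Of 16 cilium and microtubule genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.53). Without siSOX4 1 the edgeR test called 0 of these in either direction, 0 rose without siControl 2, 0 fell without siControl 1, 1 fell without siControl 2, and 1 rose and 1 fell without siSOX4 3.

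Proliferation transcripts varied more within the groups than between them. The mean of the mitosis list was 6.04, 5.98 and 5.04 log2 CPM in siControl 1, 2 and 3 and 6.24, 5.42 and 6.16 in siSOX4 1, 2 and 3. MKI67, a marker of cycling cells, was at 291 ± 115 and 446 ± 126 CPM (SD, n = 3; edgeR adjusted p = 0.27). None of 30 mitosis genes passed the test by edgeR or DESeq2, adjusted over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05 (camera adjusted p = 0.13). Of 30 DNA replication genes 1 rose and 0 fell by edgeR, and 0 adjusted over the list alone (camera adjusted p = 0.11), with 2 higher and 1 lower at an unadjusted p and by DESeq2. In the edgeR fits with 1 library left out that gene, CCNE1, cyclin E1, kept its call only without siControl 1, and 0 rose without any other single library, with 1 lower without siControl 3. FEN1, a flap endonuclease of replication, had a log2 fold change of -0.86 ± 0.26 (edgeR adjusted p = 0.064). As lists, both were past the threshold and higher in siSOX4 with no filter on low counts (camera adjusted p = 0.0082 for each) and with the replicate block (0.049 for each). The same held without siControl 1 (0.0029 for mitosis and 0.0028 for DNA replication), siControl 2 (0.014 for each) or siSOX4 2 (0.00024 and 0.00052), whereas without siControl 3 the median of the mitosis list was -0.03. These calls rest on the preset correlation: with an estimated one both lists had an adjusted p of 0.817 in all 6 libraries and of 0.730, 0.845 and 0.696 in the 3 fits with a library left out, in which edgeR called 0 of 30 mitosis genes. The libraries siControl 3 and siSOX4 2 also stood apart from the other 4 on the second principal component, which held 23.6% of the variance, while the first held 51.0% and separated siControl from siSOX4. Without these 2 libraries, which leaves 2 per group, 5573 genes changed. They were left out because they stood apart, so spread within the groups was removed by choice. Counts from that fit therefore lend no separate support to a change. This holds most for mitosis and DNA replication genes, whose list means were lowest in these 2 libraries. In that fit 17 mitosis genes rose and 1 fell, 14 DNA replication genes rose and 3 fell, and 19 p53 targets, 9 Notch and arterial genes and 8 interferon-stimulated genes fell. Of RNA quality signs in the same fit, 4 of 13 mitochondrially encoded transcripts fell, with the list past the threshold (camera adjusted p = 0.0083, and 0.723 with an estimated correlation), and 2 histone transcripts rose. The endothelial identity (0.028), TGF-beta and BMP (0.015), mesenchymal (0.010), matrix (0.0083) and junction (0.044) lists were also past it and lower, each at 0.723 with an estimated correlation.

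**Figure D4:**
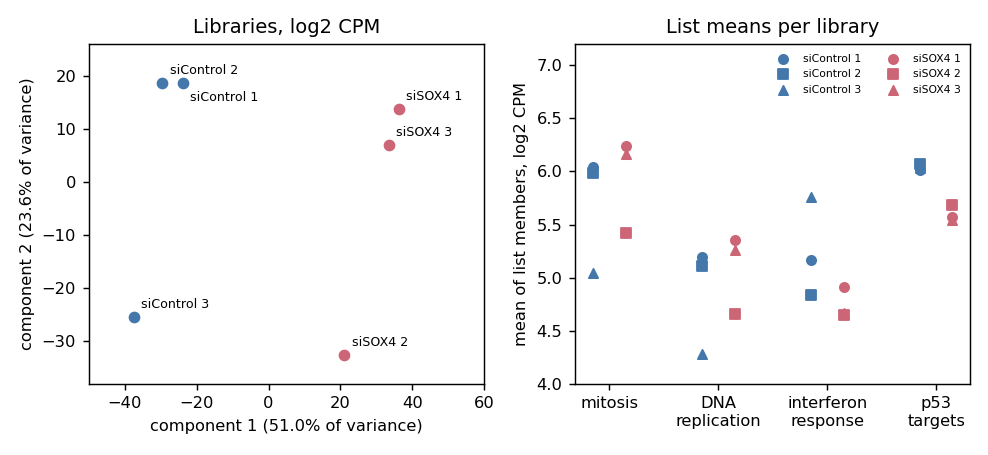
Left, the 6 libraries on the first (horizontal) and second (vertical) principal component of log2 CPM, which hold 51.0% and 23.6% of the variance. Right, mean log2 CPM of the members of 4 gene lists in each library: siControl 3 and siSOX4 2 are the lowest of their group in mitosis and DNA replication, while the p53 list separates the groups at 6.01 to 6.07 and 5.54 to 5.69.

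Markers of other cell types were few and did not move as lists. Of 7 smooth muscle and pericyte markers 1 rose (PDGFRB) and 1 fell (NOTCH3), also adjusted over the list alone (camera adjusted p = 0.38). Of 7 fibroblast markers 1 rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.80). Of 5 epithelial markers 1 rose (KRT19) and 0 fell by edgeR and DESeq2, and 3 rose and 0 fell adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p (camera adjusted p = 0.44, median 0.22). Of 13 blood cell markers only 3 were measured and 0 changed by edgeR or DESeq2, while 1 fell adjusted over the list alone and 1 was lower at an unadjusted p. These calls moved with single libraries: 0 smooth muscle markers rose without siControl 1, siSOX4 1 or siSOX4 3, 0 fell without siControl 2, siSOX4 1 or siSOX4 3, and 2 fell without siSOX4 2. In the same fits 0 fibroblast markers rose without siControl 1, siControl 2 or siSOX4 1 and 0 fell without siControl 1, siControl 2, siSOX4 1 or siSOX4 2, 0 epithelial markers rose without siControl 1, siControl 2, siSOX4 1 or siSOX4 2, and 1 blood cell marker fell without siSOX4 2. Of RNA quality signs, none of 13 mitochondrially encoded transcripts and none of 10 histone transcripts changed by edgeR or DESeq2 or adjusted over the list alone, with 0 and 2 at an unadjusted p (camera adjusted p = 0.60 and 0.30). Without siSOX4 2, 1 mitochondrial transcript fell and 2 histone transcripts rose, and the histone list was past the threshold (camera adjusted p = 0.020). Mitochondrially encoded transcripts held 5.04%, 5.15% and 5.04% of counts in siControl and 4.33%, 5.12% and 4.59% in siSOX4.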

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

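The alternatives without siControl 3 and siSOX4 2 together, with the mitosis list as a covariate and with libraries left out and an estimated correlation at once were chosen after seeing the data, and the other alternatives before. SOX4 was lower in all 16 alternatives, with log2 fold changes from -2.48 to -2.22. DESeq2 called 3351 genes, limma-voom 3126, the other scalings 3078 to 3114, no filter 3963 and the stricter filter 2851, all within 1.5 times of 3119 (upper-quartile factors gave 1429 higher and 1649 lower, the stricter filter 1415 and 1436), and no called gene changed sign under any alternative. Against a fold of 1.2, 1079 genes passed (538 higher, 541 lower), and against 1.5, 220 (95 higher, 125 lower), which follows from the stricter hypothesis. Leaving out 1 library gave 1430 to 3321 genes, with 749 to 1657 higher and 681 to 1664 lower. Without both libraries, a choice that removes spread within the groups, 5573 genes passed (2869 higher, 2704 lower), 3031 of the 3119 among them. With the covariate 6255 passed (3280 higher, 2975 lower), 3107 of the 3119 among them. The cause was not tested.

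With the replicate block 1815 genes passed (909 higher, 906 lower) and 10 lists. Deviations from the group mean correlated at 0.24, -0.27 and -0.22 in libraries with the same number. Not every library correlated best with its own number: siControl 3 and siSOX4 2 correlated at 0.47. These 2 libraries stood apart in their groups and carry different numbers. The correlations therefore cannot tell whether equal numbers share a culture or day.

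Lists past the threshold numbered 5, against 10 with no filter, 3 to 12 with 1 library left out, 13 without both libraries, 3 with the covariate, 0 with an estimated correlation and 3 in fry. The medians do not change with the set test, so the calls lost with an estimated correlation stood at -0.44 for p53 targets, -0.53 for interferon, -0.27 for Notch, -0.35 for NF-kB and -0.20 for YAP and TEAD. Of these, interferon (-0.53), NF-kB (-0.35) and YAP and TEAD (-0.20) were also lost in fry. With 1 library left out the NF-kB median ran from -0.43 to -0.14 and the YAP and TEAD median from -0.22 to -0.14, and with the covariate both calls were lost at -0.25 and -0.18. Without siControl 3 and siSOX4 2 together the calls of NF-kB (-0.076) and interferon (-0.23) held with medians nearer 0. With an estimated correlation 0 lists passed in any fit with libraries left out. The medians of the lost calls, in the order siControl 1, 2 and 3, siSOX4 1, 2 and 3 and both libraries left out, were -0.45, -0.42, -0.45, -0.42, -0.46, -0.40 and -0.47 for p53 targets and -0.61, -0.75, -0.26, -0.60, -0.51, -0.52 and -0.23 for interferon. They were -0.39, -0.30, -0.26, -0.25, -0.36, -0.35 and -0.33 for Notch, -0.34, -0.43, -0.14, -0.28, -0.41, -0.37 and -0.076 for NF-kB and -0.17, -0.20, -0.22, -0.15, -0.18, -0.14 and -0.23 for YAP and TEAD. The cause was not tested.

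Of 123 named genes 105 were called. DESeq2, limma-voom and no filter each lost 1 call. The stricter filter lost 1 of the 100 called genes that it tested and gives no result for the rest of the 105. Upper-quartile factors lost 3, the replicate block 13, single omissions 3 to 32, both libraries 8 and the covariate 5, and none reversed. Depth limits the low genes most: a count of 0 allows up to 0.0748 CPM in the shallowest library.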

Other observations

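The tests of symbol families, of the mitosis covariate, of the bounds set for the interferon list without siControl 3 (an omission planned beforehand), of an estimated correlation with libraries left out and of the 2 libraries apart from the rest were chosen only after the result was seen.

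Among 103 groups of at least 15 genes that share a symbol stem, 3 were past an adjusted p of 0.05 in camera with its preset correlation. Zinc finger genes with the stem ZNF, mostly DNA-binding proteins, were lower: of 499 measured, 69 fell and 10 rose by edgeR's adjusted p, with a median log2 fold change of -0.14 (camera adjusted p = 0.00032, and 0.999 with an estimated correlation). ZNF117 fell by 1.13 and ZNF91 by 1.13 on the log2 scale, and ZNF711 by 1.18. Without siControl 3 and siSOX4 2 together the preset correlation gave an adjusted p of 0.00045. How the counting treated reads shared between similar members was not analysed here.

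Genes of the HSPA stem, heat shock proteins of the 70 kDa family and their pseudogenes, were higher: 5 of 18 rose (camera adjusted p = 0.022, and 0.999 with an estimated correlation). HSPA1A rose by 0.81 on the log2 scale and HSPA5, the chaperone of the endoplasmic reticulum, by 0.30, a call lost without each single library but siControl 3. Of 67 genes with the stem RAB, mostly small GTPases of vesicle transport, 14 rose and 5 fell (camera adjusted p = 0.032, and 0.999 with an estimated correlation). RAB7A, of late endosomes, rose by 0.60, while RAB5B, of early endosomes, fell by 0.99 on the log2 scale. Without siControl 3 and siSOX4 2 together the RAB group had an adjusted p of 0.056.

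FEN1 had a log2 fold change of -0.86 ± 0.26 (edgeR adjusted p = 0.064), and of -1.05 ± 0.059, past the threshold, with the mitosis list as a covariate. The covariate fit was chosen after the data were seen and called 6255 genes, so the gained call lends no separate support to a change. FEN1 was at 37.3 CPM in siControl 3 and 36.0 CPM in siSOX4 1.

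The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 3119 genes, 1 of the 10 splits gave as many, and the highest of the others was 0 in edgeR, with 95 to 1640 genes at an unadjusted p under 0.05. Every other split mixes siControl and siSOX4 libraries, so a difference between the groups becomes spread within them. Few gene calls were therefore likely in those splits, and their counts are no null level for 3119. For lists the real split gave 5 in camera with its preset correlation, 8 of the 10 splits gave as many, and the highest other was 16, with siControl 1, siSOX4 1 and siSOX4 3 against the rest. With an estimated correlation 0 lists passed in any of the 10 splits, the real one included, so that setting cannot set the real split apart.

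p53 targets were lower in siSOX4 in camera with its preset correlation and in fry (adjusted p = 0.016), though not with an estimated correlation (0.795). A difference in proliferation between libraries is argued against as the whole cause, because with the mitosis list as a covariate the median log2 fold change of the list was -0.43 (camera adjusted p = 3.6e-10, against 5.7e-15 to 0.970 over the alternatives, the last with an estimated correlation and without siSOX4 1). A direct effect of SOX4 loss and a stress response to one of the siRNAs stay open, and neither was tested.

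Interferon-stimulated transcripts were lower in siSOX4 in camera with its preset correlation, a call lost with an estimated one (adjusted p = 0.817) and in fry (0.43). A raised level in 1 control library is one candidate explanation: without siControl 3 the median log2 fold change moved from -0.53 to -0.26, with a camera adjusted p of 0.0016 (1.7e-12 to 0.970 over the alternatives), which lies between the values that would have decided it. Interferon made by the control cultures after transfection is another: IFNB1 and IFNL1 to IFNL3 had 4 counts in the control libraries, all of them IFNB1 in siControl 3, against 3 in siSOX4. An interferon peak before harvest would leave no count, so the counts do not decide on interferon made by the cultures. Neither it nor a raised level in 1 control library can be told apart from an effect of SOX4 depletion.

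The libraries siControl 3 and siSOX4 2 stood apart on the second principal component. Growth state of the cultures may account for it: their mitosis list means lay 0.94 and 0.74 log2 CPM below the next library of their group, and the list's loading on that component was at percentile 100 of 10000 random lists. Lists outside proliferation also had extreme percentiles, interferon at 0 and matrix at 0.06, so an extreme percentile alone does not single out growth. Their median loadings were smaller in size, -0.0041 and -0.0037, against 0.018 for mitosis and 0.017 for DNA replication. The gaps and the loading come from the same libraries and are not separate support. For library depth, a first test on the ranks of the totals (4 of 6 from the lowest for siControl 3, 1 for siSOX4 2) did not decide. In 2 of 2 cases the library nearest in total lay on the other side of the component. These were siSOX4 1 (40662206 counts, at 13.8) against siSOX4 2 (40124105, at -32.6) and siControl 2 (42096685, at 18.6) against siControl 3 (45093052, at -25.5). Only siControl 3 and siSOX4 2 lay on the negative side, so this outcome was likely under any cause and does not decide on depth. The values show only that libraries with near totals could lie far apart on the component. Whether cell density or time in culture differed was not tested.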
